A study of Mus musculus with 20 samples.

How the data were processed

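Accessible chromatin was profiled by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, in endothelial cells sorted by flow cytometry from the brains of wild-type C57BL/6 mice. The labels describe 20 animals, each giving 1 library: 4 aged 2 months, 5 aged 6 months, 5 aged 12 months and 6 aged 18 months, with 8 males and 12 females in all. Replicates are numbered in the order the samples are listed, so the numbers name libraries and pair nothing. The library numbers carried by the samples fall into 3 runs, called library sets here. Set 1 holds 3 libraries of 18 months, set 2 holds 1 of 2 months, 5 of 12 months and 3 of 18 months, and set 3 holds 3 of 2 months and 5 of 6 months. The labels do not say that these sets are batches. Age and set overlap only in part, so values within sets are given beside pooled ones.

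The deposited data are 1 list of narrow peaks per library, so peaks were called in each animal and not on pooled reads. FastQC, Trim Galore 0.4.2, Picard 1.115 and MACS2 2.1.0 are named in the submitters' processing notes, together with the mouse build mm10, without a role or order. The aligner, the handling of reads with several matching positions, and any shift of reads for the transposase are not given in the sources used here. The names of the lists say that blacklisted regions were removed. In the files as deposited, each peak carries a score, a fold enrichment (a ratio of the pileup at the summit to the local background), a -log10 p-value, a -log10 q-value and the summit's offset in bp from the peak's start. The fold, the -log10 p and q and the score are the authors' own values per peak and were used here only to describe, rank or filter peaks within a list.

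Read depth was not used here because no counts were analysed. The fold and the p-value of a peak together fix the whole-number pileup at its summit and the local background behind it. Inverting them for 2000 peaks per library recovered a whole pileup for 100.0% of peaks in every library, with a tolerance of 0.01 on -log10 p. With p-values shuffled between peaks the share was 3.75% to 6.45%. The implied background, the 1st percentile of the backgrounds so recovered, which 9.8% to 43.8% of a library's peaks share, served as a measure of relative depth. It ran from 0.733 in 6 months replicate 3 to 3.92 in 6 months replicate 4. At a low background fewer peaks pass a q threshold, so a missing peak shows only that none was called at that depth.

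To set lists of different length side by side, each was shortened to its strongest 19749 peaks on chromosomes 1 to 19 and X, ranked by -log10 q, then -log10 p, then fold. That is as many as the shortest list holds. Consensus regions were the union of peaks overlapping by at least 1 bp over the 20 libraries, and a library called a region if any of its peaks overlapped it. Regions called in 3 to 17 libraries were tested for a trend with age by an exact two-sided test. It sets the summed age of the calling libraries against all arrangements of the same number of calls, with Benjamini-Hochberg adjustment at 0.05. Pairs of ages were compared by Fisher's exact test over regions called in at least 2 libraries and missing in at least 2. Regions called in every library of 1 age and none of the other were counted beside it. Trends of single values with age used Pearson's r and Spearman's rho with two-sided tests of 100000 permutations. The value without the 2 libraries farthest from the median age is the weakest over all equally far pairs. Differences of means in small groups used exact permutation tests. Similarity of libraries was the Jaccard index, the share of regions called by either library that both called.

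Gene positions came from RefSeq genes of GRCm38.p6, the build that mm10 names, without strand and without sequence. Transcription start sites could therefore not be told from gene ends. The planned promoter measure was replaced by a peak summit within 1000 bp of either annotated end of a protein-coding gene, over 21631 genes. The planned analysis of 22 motifs was not run. A region carries the name of the protein-coding gene with the nearest end within 50 kb, and whether it acts on that gene was not tested. The genes named in the text follow a rule fixed in advance. It takes the 10 regions per direction with the smallest trend p, 5 per direction for each age against 2 months, 5 gene ends per direction, up to 3 genes per list and 10 endothelial genes named whatever their values. A region chosen by this rule is not reported here. For lists of genes, 2 values per library were used: the share of genes with a gene-end peak, and the peaks with a summit in or within 10 kb of the genes per 10000 peaks. The 24 lists include 7 of markers of other cell types, and 455 of 456 list entries were found in the annotation. The design, tests, lists and alternatives were fixed before the data were examined, except where the text says otherwise.

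The alternatives were all deposited peaks in place of equal lists, peaks with a -log10 q of at least 5, a call only where peaks cover at least 50% of a region, no filter on the number of calling libraries, tests stratified by library set or sex, ages scored 1 to 4, gene-end windows of 500 and 2500 bp, a neighbourhood of 50 kb, and each library left out in turn. An analysis of peak ranks within the equal lists with limma 3.58.1 was added after the data had been seen.

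The trend test was tested on simulated calls for the 20 libraries. Where the share of calling libraries rose only gradually, from 5% at 2 months to 95% at 18 months, 0 of 100 changed regions passed the exact trend test, although 99 had an unadjusted p under 0.05. With step changes between 6 and 12 months mixed in, 58 of 66 such regions (87.9%) were called, beside 13 of 67 gradual ones (19.4%), and 0 of 9016 unchanged regions. Gradual changes can therefore be missed. In the simulation of 18 against 2 months, Fisher's exact test with adjustment called 0 regions at every size, although 66 of 66 step changes had an unadjusted p under 0.05. In the rank simulation limma called 41 of 100 regions changed by 2 SD, 100 of 100 changed by 4 SD and 8 of 11030 unchanged ones. All simulated libraries varied independently, without effects of library set or depth. The calls among unchanged regions therefore do not give the rate of false calls in these data. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3.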

Results

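Open chromatin was compared across adult life in brain endothelial cells, the cells that line cerebral vessels and form the blood-brain barrier, in 20 wild-type mice of 2, 6, 12 and 18 months. The series asks how endothelial chromatin differs with age, in the setting of barrier integrity and the risk of bleeding in the brain. Each animal gave 1 list of ATAC-seq peaks, of 19829 to 39421 peaks, covering 8.33 to 22.72 Mb. The background implied by the peaks' fold and p, a measure of relative depth, averaged 2.22 ± 0.855 at 2 months (SD, n = 4), 2.71 ± 1.18 at 6 months (n = 5), 3.30 ± 0.259 at 12 months (n = 5), and 2.69 ± 0.799 at 18 months (n = 6). It was higher at 12 than at 2 months (exact permutation p = 0.0159, adjusted over 3 comparisons 0.0477). Over all libraries it had no detectable relation with age (r = 0.200, permutation p = 0.40; rho = 0.206, permutation p = 0.379). That r was -0.0306 without the 2 libraries farthest from the median age, -0.0424 in set 2 and 0.177 in set 3. No pair of libraries was identical: the Jaccard index of the equal-length lists ran from 0.612 to 0.820.

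Genes that mark brain endothelium were open at every age. A peak lay within 1000 bp of an annotated end of Cdh5 (VE-cadherin, chromosome 8, 104101613 to 104144504) and Cldn5 (the main tight junction claudin, chromosome 16, 18776847 to 18778262) in all 20 libraries. The same held for Slc2a1 (the barrier glucose transporter Glut1, chromosome 4, 119108745 to 119137330) and Mfsd2a (a lipid transporter that restrains transcytosis, chromosome 4, 122946850 to 122961194). For Pecam1, Abcb1a and Vwf such a peak was called in 19 libraries. Lef1, a transcription factor of Wnt signalling, had one in 13 libraries: 2 of 4 at 2 months, 3 of 5 at 6 months, 3 of 5 at 12 months and 5 of 6 at 18 months. Plvap, a marker of fenestrated endothelium, had none in any library, although 1 to 3 peaks lay in or within 10 kb of it, and Vcam1, a leukocyte adhesion molecule, had 0 peaks in or near it in every equal-length list.

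In equal-length lists the number of peaks near these genes showed no detectable trend with age. Over all deposited peaks, in lists longer with age, r turned positive for Cdh5, Plvap and Lef1, which was not tested. Peaks in or within 10 kb of Pecam1 numbered 2.75 ± 0.5 at 2 months (SD, n = 4) and 4.0 ± 1.41 at 18 months (n = 6), and those of Cdh5 4.75 ± 0.5 and 4.17 ± 0.41. Mfsd2a had 2 in every library. The smallest adjusted permutation p over the genes whose number varied was 0.488, and the count of peaks says nothing of their height.

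Pooled over library sets, longer peak lists came mainly from animals of 18 months. The number of peaks per library was 26733 ± 6026 at 2 months (SD, n = 4), 23283 ± 2604 at 6 months (n = 5), 27508 ± 2824 at 12 months (n = 5) and 33580 ± 4786 at 18 months (n = 6). It rose with age over the 20 libraries (r = 0.603, permutation p = 0.00556; rho = 0.576, permutation p = 0.00921), and r was 0.532 without the 2 libraries farthest from the median age (permutation p = 0.0246). Within library sets the direction differed: r was 0.648 in set 2 (n = 9, permutation p = 0.0677) and -0.549 in set 3 (n = 8, permutation p = 0.162). For peaks on chromosomes 1 to 19 and X, a count chosen after the data were seen, it was 0.6895 in set 2 (permutation p = 0.0418) and -0.588 in set 3 (permutation p = 0.0894). As residuals from the implied background, also chosen later, it was 0.676 in set 2 (permutation p = 0.046; rho = 0.839, permutation p = 0.00775) and -0.742 in set 3 (permutation p = 0.0349; rho = -0.845, permutation p = 0.0349). Set 1 holds a single age, and residuals from set means gave r = 0.253 (permutation p = 0.309). Within 18 months, lists averaged 36735 peaks in set 1 and 30425 in set 2, a difference of 6310 (n = 3 each, exact permutation p = 0.2). Against 2 months, lists of 18 months were longer by 6847 peaks, which did not pass the exact permutation test (p = 0.0952, adjusted 0.286). Nor did the 775 more at 12 months (exact p = 0.738, adjusted 0.738) or the -3450 at 6 months (exact p = 0.310, adjusted 0.465). The difference at 12 months was -760.4 without 2 months replicate 1 and -557 without replicate 2.

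Within sexes, the number of peaks had r = 0.911 with age in 8 males (permutation p = 0.00253) and r = 0.356 in 12 females (permutation p = 0.254). The slopes, 895 peaks per month in males and 295 in females, were not shown to differ (permutation p = 0.144, adjusted over 12 measures 0.960).

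**Figure D1:**
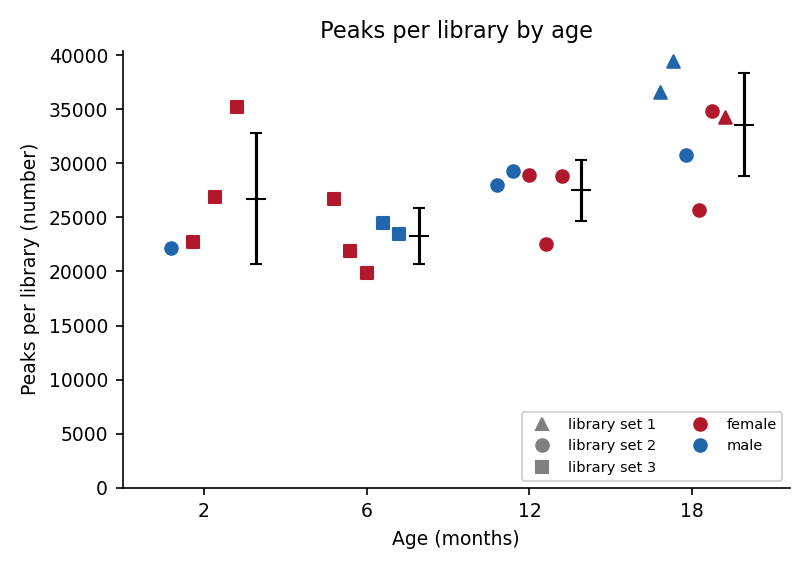
Number of deposited peaks per library (vertical axis) by age in months (horizontal axis), with colour for sex, shape for library set, and bars for the mean and SD of each age. Libraries of 18 months reach 39421 peaks and those of 6 months stay at or below 26735.

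The share of peaks at gene ends showed no detectable trend with age in lists of equal length. It averaged 41.9 ± 0.615% at 2 months (n = 4), 40.9 ± 0.511% at 6 months (n = 5), 42.1 ± 0.442% at 12 months (n = 5) and 41.5 ± 1.04% at 18 months (n = 6). The difference of 6 minus 2 months was -1.023 points (exact permutation p = 0.0317, adjusted over 3 comparisons 0.0951). Over all ages r was near 0 (r = 0.0455, permutation p = 0.849; rho = -0.0027, permutation p = 0.992). Without the 2 libraries farthest from the median age r was 0.0093, and it was -0.202 in set 2 and -0.653 in set 3. It lay below 0 without 6 months replicate 3 (-0.0564) or 4 (-0.0116) or 18 months replicate 3 (-0.0711) or 4 (-0.0127). Over all deposited peaks the share fell with age (r = -0.573, permutation p = 0.00939; rho = -0.574, permutation p = 0.00967), from 36.7 ± 5.28% at 2 months (n = 4) to 31.5 ± 3.32% at 18 months (n = 6), as lists grew longer. That r was -0.468 without the 2 farthest libraries, -0.698 in set 2 and 0.456 in set 3.

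Libraries of 12 and 18 months resembled each other more than the younger ones did. Over all pairs the mean Jaccard index was 0.764 within ages and 0.734 between them, a difference of 0.0295 (permutation p = 1e-05, the smallest that 100000 permutations can give). Pairs of 12 months averaged 0.790, pairs of 18 months 0.792 and pairs of 12 with 18 months 0.777, against 0.729 within 2 months and 0.717 within 6 months. Libraries of 2 and 6 months were no closer to their own age than to 12 months: pairs of 2 with 12 months averaged 0.734 and of 6 with 12 months 0.729, and those of 2 with 18 months 0.730. The lowest means were those of 2 with 6 months (0.715) and 6 with 18 months (0.713). For library sets the same difference was 0.0122 (0.749 against 0.737, permutation p = 0.0761). These permutations mix ages across sets. Among pairs within sets, with ages permuted within sets, a test added later, the difference between pairs of 1 age and of different ages was 0.0225 (0.761 against 0.739, permutation p = 0.0336). It was 0.0379 in set 2 (permutation p = 0.00209) and 0.0019 in set 3 (permutation p = 0.982). All pairs of the single 2 months library in set 2 count as pairs of different ages. The value of set 2 therefore need not come from 12 against 18 months, whose pairs averaged 0.777 over all sets.

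Single regions near Arntl, Slc20a1, Xpc and H2-Q6 were called in most older and few younger animals. Of 10640 regions tested, 63 were called more often with age and 208 less often by the exact trend test, and 1747 had an unadjusted p under 0.05 (908 more, 839 less). The balance turned in lists of unequal length, which are longer at older ages: 743 more and 331 less often over all deposited peaks, and 716 and 297 with a -log10 q of at least 5. A region on chromosome 7 (113172273 to 113172921), 5550 bp from an end of Arntl, the core clock gene also called Bmal1, was called in 0 of 4 libraries at 2 months and 1 of 5 at 6 months. At 12 months 5 of 5 and at 18 months 6 of 6 called it (exact trend p = 7.94e-05, adjusted 0.0117). Near Slc20a1, a phosphate transporter, the region at 129166299 to 129167263 of chromosome 2 was called in all libraries of 12 and 18 months and no younger one (exact p = 1.19e-05, adjusted 0.00295). It was the only one of the 63 with that pattern. On chromosome 6, 91488704 to 91489258, 47 bp from an end of Xpc, which recognises DNA damage for excision repair, the counts were 0, 0, 3 and 6 libraries at 2, 6, 12 and 18 months. The counts were the same for regions at Zfp710, a zinc finger gene (chromosome 7, 80092221 to 80093015), and 3550 bp from Tmem270 (chromosome 5, 134897454 to 134898043), all 3 with an adjusted exact p of 0.0117.

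Regions found mainly at 18 months included the end of H2-Q6, a class I major histocompatibility gene. The region at 35424644 to 35424979 of chromosome 17 was called in 0 of 4, 0 of 5, 1 of 5 and 6 of 6 libraries at 2, 6, 12 and 18 months, as was a region inside Mturn (chromosome 6, 54699229 to 54699832). Each had an exact trend p of 0.000129 (adjusted 0.0117). H2-Q6 has near-identical neighbours, so the position of its reads is uncertain. A region 4140 bp from Ptchd3 (chromosome 11, 121847578 to 121848327) had 0, 1, 5 and 6 calling libraries. A region 9085 bp from the predicted gene Gm51591 and another at Gm51593 (chromosome 8, 55356871 to 55357220 and 55380305 to 55381319) had 1, 0, 5 and 6 (adjusted exact p = 0.0117 for all 3). The Gm genes had no direction within library sets.

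Regions called less often with age were narrow and mostly far from the ends of protein-coding genes. Of the 208, 42 were called in all 9 libraries of 2 and 6 months and in none of 12 and 18 months. Examples were regions inside Hsd11b1, whose enzyme regenerates active glucocorticoid (chromosome 1, 193227692 to 193228038), and 10803 bp from Myct1, a target of Myc expressed in endothelium (chromosome 10, 5582613 to 5582925). Others lay inside Mier3 (chromosome 13, 111698231 to 111698621), 3177 bp from Eps8l1 (chromosome 7, 4457138 to 4457461) and 8494 bp from Slc25a54, a mitochondrial carrier (chromosome 3, 109071712 to 109072005). The same calls were found near Olfr816 (chromosome 10, 129927207 to 129927558), Klhl4 (chromosome X, 114497326 to 114497681), Krtap4-6 (chromosome 11, 99715813 to 99716515), Gm51415 (chromosome 1, 15396295 to 15396678) and Gm38664 (chromosome 1, 181266032 to 181266329). For each of these 10 the exact trend p was 1.19e-05 (adjusted 0.00295).

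Only 6 of the 208 (2.9%) lay within 1 kb of an end of a protein-coding gene, against 20.7% of the other tested regions (odds ratio 0.11, Fisher's exact p = 9.64e-14, adjusted over 10 tests 2.41e-13). Another 114 (54.8%) lay over 50 kb from any such end, against 25.3% (odds ratio 3.58, adjusted Fisher's exact p = 1.47e-18). Their median width was 375 bp, against 665 bp for the 63 regions gained and 587 bp for all tested. The first 35 Mb of chromosome 1 held 53 of them (25.5%) and 2.4% of the other tested regions (odds ratio 13.65), a stretch chosen after these positions were seen, so that no test of it is given. Of the 63 gained regions, 0 lay there and 11 (17.5%) lay within 1 kb of a gene end, against 20.4% of the others (Fisher's exact p = 0.641).

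Stratified by library set, the exact trend test called 0 regions after adjustment and 278 at an unadjusted p under 0.05. With 1 young library in set 2 that test has little power: the 42 lost regions and the Slc20a1 region, which part the 2 younger from the 2 older ages in full, can reach only an exact p of 0.222 within sets. The calls it loses therefore do not show that the differences are absent within sets. Within sets 58 of the 63 and 192 of the 208 kept their direction, 9 and 12 with an unadjusted p under 0.05. The regions were chosen for their trend on these same libraries, so this agreement is partly built in and is no support for a change within sets. For the 42 lost regions and the Slc20a1 region the choice fixes the direction within sets. The count of gained regions moved by over 1.5 times when a single library was left out: to 29, 28, 32 and 105 without 2 months replicates 1, 2, 3 and 4. It was 38, 34 and 36 without 6 months replicates 2, 4 and 5, and 40, 37 and 37 without 18 months replicates 1, 2 and 6. That of lost regions moved to 327 without 2 months replicate 4 and to 136 without 18 months replicate 6. Of the 10 gained regions named above, 6 passed over all deposited peaks, where those near Slc20a1 (adjusted exact p = 0.074), Ptchd3 (0.14), Mturn and Tmem270 (0.074 each) did not. With a -log10 q of at least 5, 8 passed, and with 50% of a region covered 5, without Slc20a1 (0.232), Ptchd3, Mturn, Zfp710 and Gm51593. Mturn also failed without 6 months replicate 3 (0.0759). Of the 10 lost regions named, 9 passed in each of these settings: Slc25a54 did not over all deposited peaks (0.14) or with a -log10 q of at least 5 (0.131), nor Krtap4-6 with 50% covered (0.232).

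**Figure D2:**
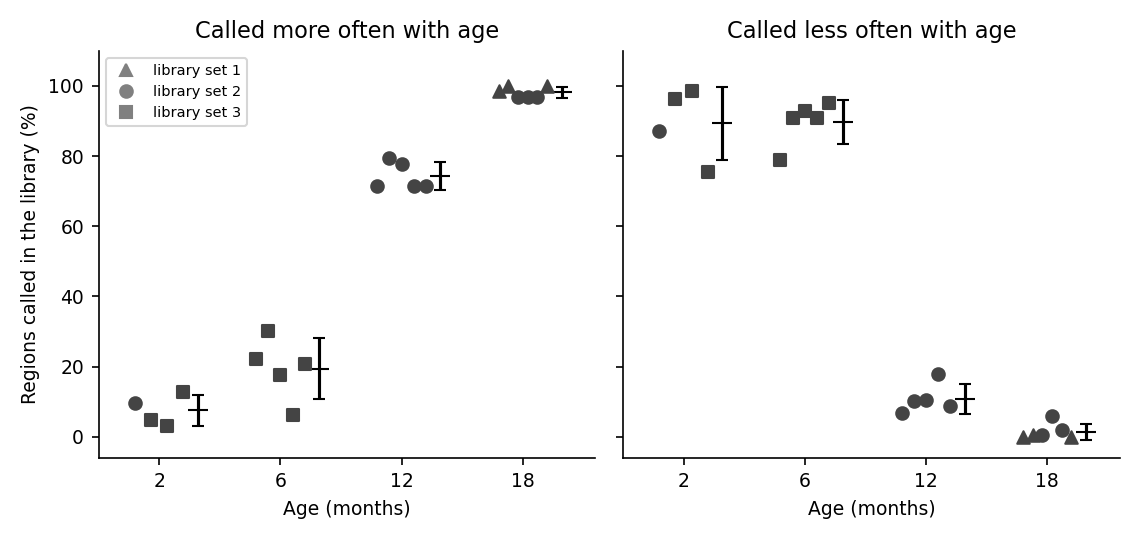
Share of the 63 regions called more often with age (left) and of the 208 called less often (right) that each library called, in percent, by age in months; shapes are library sets, bars the mean and SD of each age. The regions were chosen on these libraries, and the library of 2 months in set 2 called 87.0% of the lost regions.

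The first 35 Mb of chromosome 1, picked because regions called less often with age in these libraries gather there, held fewer peaks in the older ones. The values below describe that pattern and do not test it. In equal-length lists the stretch held 282 ± 101 peaks at 2 months (SD, n = 4), 364 ± 74.2 at 6 months (n = 5), 177 ± 27.6 at 12 months (n = 5) and 134 ± 24.6 at 18 months (n = 6). These were 1.43%, 1.84%, 0.898% and 0.678% of peaks. Over the 20 libraries r of the share with age was -0.731 (rho = -0.815), and -0.696 without the 2 libraries farthest from the median age. Within set 2 r was -0.724 (n = 9), within set 3 it was 0.367 (n = 8), and residuals from set means gave -0.107, so the pooled relation was not seen within sets as a whole.

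**Figure D3:**
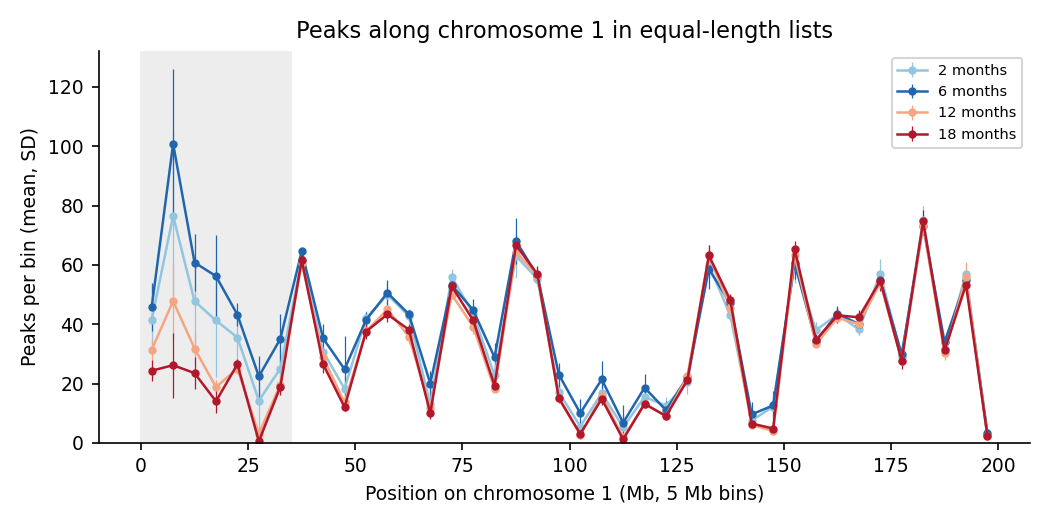
Mean number of peaks (vertical axis, with SD) in bins of 5 Mb along chromosome 1 (horizontal axis, Mb) for the 4 ages in lists of 19749 peaks; the first 35 Mb are shaded. In the bin from 5 to 10 Mb the means are 76.5, 100.8, 47.8 and 26.17 at 2, 6, 12 and 18 months.

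Against 2 months alone, more regions were called in the young animals only than in the old only. Between 18 and 2 months, 59 regions were called in all 6 and none of the 4 libraries, and 108 the other way. The first count needs 6 shared calls and the second 4, so the 2 counts do not ask for the same agreement. Those of 18 months with the lowest p included 1 at H2-Q6 and 1 inside Trim71 (chromosome 9, 114515127 to 114516057). Others lay 35119 bp from Sdc3, a heparan sulfate proteoglycan (chromosome 4, 130861437 to 130862284) and near Ptchd3. Those of 2 months were near Slc25a54, Mier3, Eps8l1 and Olfr816 and inside Casp8, an initiator of cell death (chromosome 1, 58814487 to 58814830), which 4 libraries of 2 and 4 of 6 months called. Each had a Fisher's exact p of 0.00476, the smallest this design allows, and an adjusted p of 0.266. Fisher's exact test called 0 of 9314 regions after adjustment and 806 at an unadjusted p under 0.05. Of these, 366 were called more often at 18 months and 440 less often, a smaller imbalance. The 167 separated regions became 251 without 2 months replicate 1 and 376 without replicate 4.

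At 12 against 2 months, 62 regions were called in all 5 and none of the 4 libraries, and 102 the other way. Those of 12 months lay inside Sestd1 (chromosome 2, 77268276 to 77269240), at Zfp951 (chromosome 5, 104859660 to 104860479) and near Ptchd3. Others lay 23411 bp from Pdp1, a phosphatase that activates pyruvate dehydrogenase (chromosome 4, 11989861 to 11990924), and 32255 bp from Tm4sf1, an endothelial surface protein (chromosome 3, 57252390 to 57253356). Those of 2 months lay near Slc25a54, Mier3, Casp8 and Eps8l1 and inside Arid4a (chromosome 12, 71080645 to 71080998). Each had a Fisher's exact p of 0.00794 (adjusted 0.413). Fisher's exact test called 0 of 8532 regions after adjustment and 830 at an unadjusted p under 0.05 (393 more often at 12 months, 437 less often). The 164 separated regions became 314 without 2 months replicate 1 and 332 without replicate 4.

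Fewer regions separated 6 from 2 months: 24 were called in all 5 and none of the 4 libraries, and 17 the other way. Those of 6 months were inside Trim71, near Camk2g (chromosome 14, 20803348 to 20803934), at Mxra7 (chromosome 11, 116827147 to 116828258), near Ola1 (chromosome 2, 73059729 to 73060675) and inside Vac14 (chromosome 8, 110711147 to 110712515). Those of 2 months were at Zfp626 (chromosome 7, 27804405 to 27805132) and Agk (chromosome 6, 40325052 to 40325865) and inside Acad12 (chromosome 5, 121601737 to 121602295), Nin (chromosome 12, 70029169 to 70029768) and Dock9 (chromosome 14, 121568898 to 121569482). Fisher's exact test called 0 of 9412 after adjustment (smallest adjusted p 0.944) and 411 at an unadjusted p under 0.05. The separated regions numbered 105, 88, 90 and 78 without 2 months replicates 1 to 4 and 85, 62, 120 and 63 without 6 months replicates 1 to 4.

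Ages were also compared inside library sets. In set 2, 71 regions were called in all 3 libraries of 18 months and none of the 5 of 12 months, and 68 the other way. In set 3, 32 were called in all 5 libraries of 6 months and none of the 3 of 2 months, and 73 the other way. Within 18 months, 120 regions were called in the 3 libraries of set 1 alone and 105 in the 3 of set 2 alone. Fisher's exact test called 0 regions after adjustment in each. At an unadjusted p under 0.05 it called 139 of 6838 in set 2, 105 of 8393 in set 3 and 0 of 4980 within 18 months, where p cannot go below 0.1. The 139 separated regions of set 2 became 210 without 12 months replicate 5 and 300, 277 and 377 without 18 months replicates 3, 4 and 5. The 105 of set 3 became 298, 284 and 231 without 2 months replicates 2, 3 and 4, and 185 and 249 without 6 months replicates 1 and 3. The 225 within 18 months became 394, 500, 486, 439, 594 and 446 without replicates 1 to 6.

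No single gene end passed the exact trend test. Of 21631 protein-coding genes, 6893 had a gene-end peak in all 20 libraries, 11283 in none and 2009 were tested. By the exact trend test 0 passed after adjustment (smallest adjusted p 0.0532) and 181 had an unadjusted p under 0.05, 121 called more often with age and 60 less often. With the lowest p were Tmem43, a nuclear envelope protein (chromosome 6, 91473707 to 91488463), with 0, 0, 3 and 6 libraries at 2, 6, 12 and 18 months. The region named above for Xpc starts within 1000 bp of that end of Tmem43 and had the same counts. Both names may therefore stand for the same peak. H2-Q6 had 0, 0, 1 and 6, and Gm51593 had 1, 0, 5 and 6. Wdr55 (chromosome 18, 36760222 to 36763708) and Cdk10, a cyclin-dependent kinase (chromosome 8, 123224841 to 123232256), had 0, 0, 2 and 6 each. In the other direction were Slc22a23, an organic ion carrier (chromosome 13, 34179158 to 34345275), with 4, 5, 1 and 0 libraries, and Gm52420 (chromosome X, 71882005 to 71883666) with 3, 4, 0 and 0. Ggnbp1 (chromosome 17, 27018035 to 27036378) and Auts2 (chromosome 5, 131437333 to 132543220) had 4, 3, 1 and 0, and Igdcc3 (chromosome 9, 65141154 to 65187031) had 4, 4, 4 and 0. With windows of 2500 bp 9 genes passed, and with all deposited peaks 11. Without 12 months replicate 2, 1 passed, Slc22a23 (adjusted exact p = 0.0427).

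No list of genes passed adjustment for neighbouring peaks. Of 24 lists, 0 passed for peaks in or within 10 kb of their genes, by permutation tests of r with Benjamini-Hochberg adjustment over 24, and 7 had an unadjusted p under 0.05. Peaks around the 15 caveolae genes numbered 17.7 ± 0.72 per 10000 at 2 months (SD, n = 4) and 19.3 ± 0.98 at 18 months (n = 6; r = 0.581, permutation p = 0.00853, adjusted 0.0810; rho = 0.605, permutation p = 0.00566). That r was 0.511 without the 2 libraries farthest from the median age, 0.365 in set 2 and -0.129 in set 3, and residuals from set means gave 0.203 (permutation p = 0.457). For the 18 genes of cerebral hemorrhage and cavernoma the numbers were 27.7 ± 1.72 and 30.7 ± 1.46 (r = 0.488, permutation p = 0.0255, adjusted 0.122; rho = 0.486, permutation p = 0.0313), with 0.363 without the 2 farthest, 0.729 in set 2, 0.111 in set 3 and 0.490 as residuals (permutation p = 0.0415). Those of Notch signalling were 17.3 ± 0.48 and 16.4 ± 0.52 (r = -0.469, permutation p = 0.0378, adjusted 0.151; rho = -0.487, permutation p = 0.0305; -0.362 without the 2 farthest, -0.391 in set 2, -0.063 in set 3, residuals -0.276, permutation p = 0.311). Those of oxidative stress and mitochondria were 23.8 ± 0.58 and 21.3 ± 1.15 (r = -0.450, permutation p = 0.0458, adjusted 0.157; rho = -0.563, permutation p = 0.0109; -0.260 without the 2 farthest, -0.609 in set 2, -0.747 in set 3, residuals -0.534, permutation p = 0.00502).

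Of the lists of markers of other cell types, 3 had an unadjusted p under 0.05 and did not pass either. Around 20 genes of microglia and macrophages there were 4.18 ± 0.86 peaks per 10000 at 2 months (SD, n = 4) and 5.15 ± 0.59 at 18 months (n = 6; r = 0.586, permutation p = 0.00554, adjusted 0.0810; rho = 0.551, permutation p = 0.0130). Without the 2 farthest libraries r was 0.478, in set 2 0.435, in set 3 0.178 and as residuals from set means 0.330 (permutation p = 0.205). Around 16 neuronal genes there were 2.15 ± 0.86 and 3.29 ± 0.70 (r = 0.561, permutation p = 0.0101, adjusted 0.0810; rho = 0.526, permutation p = 0.0186; 0.433 without the 2 farthest, 0.503 in set 2, 0.269 in set 3, residuals 0.395, permutation p = 0.112). Around 14 astrocyte genes there were 3.92 ± 0.64 and 2.87 ± 0.26 (r = -0.539, permutation p = 0.0152, adjusted 0.0911; rho = -0.551, permutation p = 0.0130; -0.374 without the 2 farthest, -0.696 in set 2, -0.553 in set 3, residuals -0.654, permutation p = 0.0140), but r was 0.265 over all deposited peaks. The microglia list passed without 2 months replicate 4 (adjusted permutation p = 0.0151) and the neuron list without 18 months replicate 5 (adjusted permutation p = 0.0454).

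The remaining lists had an adjusted permutation p of 0.336 or more for neighbouring peaks. As residuals from set means 0 of the 24 passed adjustment either (smallest adjusted permutation p 0.12), and lymphocyte and leukocyte markers had r = 0.372 (permutation p = 0.0407). Peaks per 10000 at 2 and 18 months were 44.3 ± 2.36 (SD, n = 4) and 46.2 ± 2.55 (n = 6) for endothelial identity, 33.7 ± 1.21 and 34.4 ± 1.72 for tight and adherens junctions. They were 38.9 ± 2.46 and 40.3 ± 0.70 for barrier transporters and 37.0 ± 2.07 and 37.8 ± 2.37 for the Wnt/beta-catenin barrier program. Genes of leukocyte adhesion and NF-kB had 21.8 ± 1.85 and 23.0 ± 1.74, and those of interferon response and antigen presentation 21.3 ± 1.31 and 23.0 ± 1.23. The numbers were 34.7 ± 2.05 and 33.7 ± 2.14 for TGF-beta and BMP signalling and 28.6 ± 3.11 and 30.5 ± 1.26 for basement membrane and matrix. Angiogenesis and tip cells had 19.4 ± 1.45 and 20.3 ± 1.72, arterial genes 14.7 ± 0.83 and 15.0 ± 0.69, and venous genes 9.75 ± 1.67 and 10.4 ± 1.05. Immediate early and stress genes 28.1 ± 2.36 and 28.4 ± 0.72, and cell cycle and senescence 19.8 ± 0.72 and 19.5 ± 1.10. Pericyte and smooth muscle markers had 3.04 ± 1.09 and 2.78 ± 0.42, and oligodendrocyte markers 1.90 ± 0.25 and 2.28 ± 0.70. Erythroid markers had 2.28 ± 0.29 and 2.19 ± 0.26, and lymphocyte and leukocyte markers 3.92 ± 0.48 and 4.98 ± 0.50.

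For gene-end peaks over all libraries, 0 of 24 lists passed and 0 had an unadjusted permutation p under 0.05 (adjusted p 0.988 or more). As residuals from set means, lymphocyte and leukocyte markers had r = 0.447 (unadjusted permutation p = 0.00806), with 0.815 in set 2 and 0.652 in set 3. Their r over all libraries was 0.0856 (permutation p = 0.734), and no other list had an unadjusted p under 0.05 as residuals. A gene-end peak was found at 2 and 18 months for 76.0 ± 2.08% (SD, n = 4) and 75.7 ± 1.70% (n = 6) of endothelial identity genes, and for 72.7 ± 0.0% of barrier transporter genes at both. The shares were 7.50 ± 2.89% and 9.17 ± 2.04% for microglia markers, 6.25 ± 5.10% and 8.33 ± 5.10% for neuron markers and 7.14 ± 0.0% and 5.95 ± 2.92% for pericyte markers. Over all deposited peaks 4 lists passed, in lists of peaks that were themselves longer with age: venous (37.5 ± 4.81% at 2 and 56.9 ± 8.19% at 18 months, adjusted permutation p = 0.0312), leukocyte adhesion and NF-kB, angiogenesis, and arterial genes (adjusted permutation p = 0.0442 each).

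Of single regions inside the lists, those near Smad5, Tgfbr3, Ctnnd1 and Flt1 passed over all regions in equal-length lists, and none of these 4 over all deposited peaks (adjusted exact p = 0.074, 0.14, 0.156 and 0.0862) or stratified by library set (0.986 to 0.991), where the pattern of Smad5 can reach only an unadjusted p of 0.222 and the differences between 18 and 2 months are the same by construction. With a -log10 q of at least 5 only Tgfbr3 passed (0.0464). Tgfbr3 failed with 50% of a region covered (0.0706), with regions called in any number of libraries (0.0668) and with ages scored 1 to 4 (0.0695), and Flt1 with any number of libraries (0.0796) and stratified by sex (0.0637). With 1 library left out, the adjusted p rose to as much as 0.103 for Tgfbr3 and 0.0706 for Flt1, and stayed under 0.05 for Smad5 and Ctnnd1. In the list of TGF-beta and BMP signalling, 2 of 40 tested regions passed adjusted over the list alone and 2 over all regions. One inside Smad5, a BMP effector (chromosome 13, 56713512 to 56713860), was called in 4, 5, 0 and 0 libraries at 2, 6, 12 and 18 months (adjusted exact p = 0.00295 over all regions). One 17743 bp from Tgfbr3, a co-receptor (chromosome 5, 107087920 to 107088824), was called in 1, 0, 4 and 6 (0.0329). In the list of tight and adherens junctions, 1 of 27 passed adjusted over the list alone and 1 over all. It lay 19828 bp from Ctnnd1, the catenin that stabilises cadherins (chromosome 2, 84566927 to 84567268), with 4, 5, 4 and 0 libraries (adjusted exact p = 0.0117 over all regions). Among 44 regions of endothelial identity, 1 passed adjusted over the list alone and 1 over all. It lay 18275 bp from Flt1, a VEGF receptor (chromosome 5, 147744713 to 147745658), with 0, 2, 4 and 6 (adjusted exact p = 0.0392 over all regions). In leukocyte adhesion and NF-kB 1 of 25 passed adjusted over the list alone and 0 over all. It lay at an end of Nfkb1 (chromosome 3, 135690467 to 135692109), with 4, 5, 4 and 1 libraries (exact trend p = 0.0016, adjusted 0.0544 over all). In immediate early and stress genes 1 of 24 passed adjusted over the list alone and 0 over all. It lay 6718 bp from Fosb, an AP-1 subunit (chromosome 7, 19316836 to 19317234), with 0, 0, 3 and 5 (exact trend p = 0.00151, adjusted 0.0544 over all).

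In the other lists 0 regions passed the exact trend test, adjusted over the list alone or over all regions. The further regions that the naming rule took from the lists had an unadjusted exact p under 0.05 and did not pass either adjustment. They are given as calling libraries at 2, 6, 12 and 18 months. Regions near Erg (1, 2, 4 and 6) and Tek (2, 1, 3 and 6) belonged to endothelial identity, and those near Slc6a6 (0, 1, 3 and 5), Abcc4 (0, 4, 2 and 6) and Slc22a8 (3, 1, 5 and 6) to barrier transporters. In the Wnt list were Tnfrsf19 (2, 0, 2 and 6), Nkd1 (2, 3, 5 and 6) and Tcf7 (2, 2, 0 and 0), and in caveolae and transcytosis Cav2 (1, 4, 5 and 6), Picalm (0, 3, 5 and 5) and Pacsin2 (0, 0, 1 and 3). Regions near Vwf (0, 0, 0 and 3), Smad3 (1, 2, 2 and 6), Timp3 (2, 3, 5 and 6), Sparcl1 (0, 1, 1 and 4), Foxc1 (1, 3, 4 and 6), Nrp2 (1, 1, 0 and 6), and Angpt2 (1, 3, 4 and 6) had more calling libraries at 18 than at 2 months. So did those near Aurkb (0, 2, 4 and 5), Nrarp (0, 1, 2 and 4) and Hes1 (0, 0, 2 and 3). Regions near Vegfc (3, 3, 0 and 0), Flrt2 (4, 5, 5 and 3), Klf6 (2, 3, 0 and 0), Cdkn1a (2, 4, 1 and 0), Gclc (3, 4, 4 and 0) and Foxo1 (4, 4, 5 and 2) had a lower share. Among markers of other cells were Spi1 of microglia (1, 1, 2 and 5) and Zap70 (1, 4, 5 and 6) and Cd2 (0, 1, 4 and 4) of lymphocytes.

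Sex differences sat on the X chromosome. Fisher's exact test over 10640 regions called 9, all on X and all in 12 of 12 female and 0 of 8 male libraries (exact p = 7.94e-06, adjusted 0.00938). It called 0 of 10227 on autosomes, where 215 had an unadjusted p under 0.05. On X 49 of 413 did, 46 of them called more in females. Firre, a long noncoding RNA gene tied to the inactive X (chromosome X, 50563120 to 50635321), held 5 of the 9 and another lay at 50549642 to 50550789, beyond its end. The other 3 lay inside 4933407K13Rik, a noncoding gene also called Dxz4 and known as a contact point of the inactive X, between 75729597 and 75759667. Peak summits inside Firre numbered 12.5 ± 3.45 in females (SD, n = 12) and 0 in all 8 males (permutation p = 2e-05, adjusted over 4 tests 8e-05). A peak over its end at 50635321 was called in all 12 female and 8 male libraries. Of equal-length lists, 2.65 ± 0.22% of peaks lay on X in females (n = 12) and 2.23 ± 0.09% in males (n = 8; permutation p = 0.00015, adjusted 0.0003). Peaks on Y numbered 342 to 1833 in males and 0 to 41 in females, so each library went with its labelled sex. With at least 50% of a region covered, 0 regions differed by Fisher's exact test after adjustment.

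**Figure D4:**
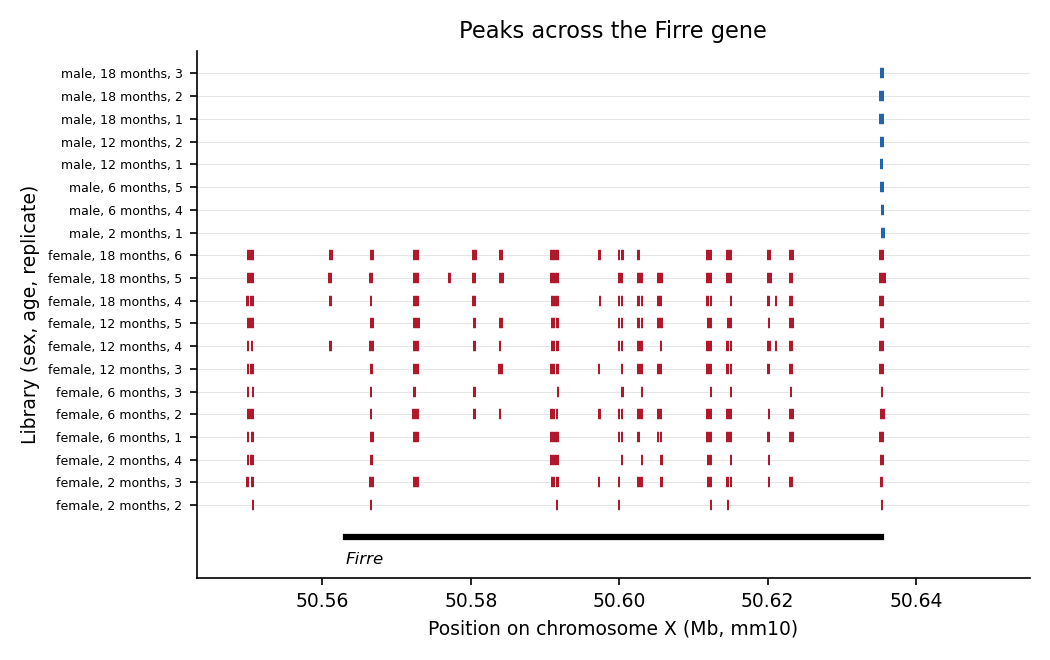
Peaks of the equal-length lists across Firre on chromosome X (horizontal axis, Mb on mm10), 1 row per library, females in red and males in blue, with the annotated gene as a black bar. All 12 female libraries hold peaks along the gene, and the 8 male libraries hold a peak only over its end at 50635321.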

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

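The tests of library set, of held-out libraries and of the first 35 Mb of chromosome 1 were chosen after the results were seen. Regions with an age trend numbered 271 in both directions, and chance can be excluded: 1 of 100 assignments of the ages, the real one, gave as many, and the highest other gave 0. When ages were reassigned only within library sets, 5 of 100 draws, the real one included, gave as many regions. The highest gave 353, so library set may account for a count of this size. Lost regions were picked again without set 2, as the 142 called in all libraries of set 3 and none of set 1. In set 2 these were called at 21.1 ± 9.93% at 18 months (SD, n = 3) and 31.1 ± 6.76% at 12 months (n = 5; exact permutation p = 0.125), and at 81.7% in its 1 library of 2 months. Age and library set therefore cannot be told apart for lost regions, since set 2 holds a single young library.

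Regions gained with age were tested in the same way, and here the tables argue against library set as the whole cause. The 73 regions called in all libraries of set 1 and none of set 3 were called at 49.8 ± 8.03% at 18 months (SD, n = 3) and 34.8 ± 4.71% at 12 months (n = 5) inside set 2 (exact permutation p = 0.0179, the smallest this design allows), higher in each of the 3 than in any of the 5. After the number of peaks per library was taken out, the difference was 9.04 percentage points (exact permutation p = 0.0357), against longer lists as the whole cause. The library of 2 months in set 2 called 20.5%. A change of endothelial chromatin between 12 and 18 months may therefore contribute, as a hypothesis found and tested on the same animals. Inside set 2 the library numbers of 18 months all come before those of 12 months. The implied background there was 1.77, 1.71 and 3.04 at 18 months, below the 3.09 to 3.74 of 12 months. The median fold of peaks was 6.56, 7.08 and 5.94 at 18 months, above the 5.56 to 5.80 of 12 months. Age therefore cannot be told apart there from the order of the library numbers, from depth or from enrichment.

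The fall of peaks in the first 35 Mb of chromosome 1 was set against depth, a general change at chromosome starts and misplaced reads of repeats. Depth, as the implied background measures it, is argued against as the whole cause. Libraries of 6 and 18 months had like backgrounds, 2.71 ± 1.18 (SD, n = 5) and 2.69 ± 0.799 (n = 6). They held 364 ± 74.2 and 134 ± 24.6 peaks in that stretch. Taking out the implied background moved r with age only from -0.731 to -0.716. The background itself hardly follows age (r = 0.200), so that correction alone decides little. A general change is argued against by the other 18 autosomes, whose median r in their first 35 Mb was -0.130 (interquartile range 0.542) against -0.731. Reads of repeats placed at chance positions could contribute: in the 12 females, which have no Y, peaks on Y went with the share of chromosome 1 after age means were taken out (r = 0.814, permutation p = 0.00612; rho = 0.860, permutation p = 0.0280), and without the 2 libraries farthest from the median share r was 0.670 (n = 10, permutation p = 0.0558; rho = 0.770, permutation p = 0.2496). The 2 females with the lowest implied background were 6 months replicate 3 (0.733) and 2 months replicate 2 (1.21). They had the most peaks on Y among females, 41 and 25, and the highest shares, 2.47% and 2.14%. That relation therefore does not tell misplaced reads from depth. Age itself, a part played by depth, library set and a chromosome segment that differs between groups of C57BL/6 animals stay open, the last untested.

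Single libraries stood apart from the others of their age in 5 of 48 groups of values examined, where chance alone marks about 1 in 20. 12 months replicate 4 had 22530 peaks, against 27977 to 29294 in the others of its age. 12 months replicate 3 had an implied background of 3.74, the next being 3.27. 18 months replicate 5 had a median peak width of 546 bp, the next being 493 bp. 6 months replicate 3, the library with the lowest implied background, had 23.3 peaks per 10000 near genes of cerebral hemorrhage and cavernoma, the next being 29.9, and 18.2 near genes of oxidative stress and mitochondria, the next being 21.8. Chromosome Y, used above only to check sex, carried up to 25 peaks in females of 2 months, 41 at 6 months, 3 at 12 months and 10 at 18 months. Mitochondrial DNA held 2 to 5 peaks per library and unplaced sequence 35 to 109. For 12 measures, change per month was compared between the sexes, and 0 passed by permutation test with adjustment (each adjusted p 0.960), nor did any have an unadjusted p under 0.05 (smallest 0.144).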

How the results depend on the processing

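The rank analysis, the values without the first 35 Mb of chromosome 1 and those on peak number by chromosome and by implied background and on similarity within sets were chosen after the data were seen. Under alternatives other than leaving out a library, 45 of 71 values of the comparisons and 480 of 554 of single genes and regions kept their direction and side of the threshold (counts within 1.5 times); with 1 library left out, 277 of 330 and 1851 of 1890 did. Where values below moved, the cause was not tested. No paired analysis was possible because the replicate numbers were given in listing order and pair no animals. The motif analysis and its 4 alternatives were not run. Depth limits what a missing peak can show.

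With all deposited peaks, 743 regions were called more often and 331 less often with age, which turns the balance of gains and losses, 290 separated 18 from 2 months, 248 separated 12 from 2 months, 242 separated 2 from 6 months in set 3 and 659 the sets within 18 months. The gene-end share then fell (r = -0.573), as it did with a -log10 q of at least 5 (-0.565), 11 gene ends and 4 lists of gene ends passed, and r turned for peaks near Cdh5 (0.367), Plvap (0.442), Lef1 (0.559) and the astrocyte list (0.265). The direction with age turned for Tcf7 (50.0 points between 2 and 18 months) and Klf6 (16.7). It did so also with a -log10 q of at least 5, where 716 regions were called more often. Covering 50% of a region left 0 sex differences by Fisher's exact test. Testing regions called in any number of libraries left 24 more and 128 less often. Stratified by set, 0 and 0 passed the exact trend test, with 278 at an unadjusted p under 0.05 in a test of little power, and Slc22a8 turned (-25.0 points). Residuals from set means weakened the trend in peak number (r = 0.253). Gene-end windows of 2500 bp passed 9 genes; a neighbourhood of 50 kb passed 1 list, caveolae (adjusted permutation p = 0.0360), and turned Cldn5 (0.101).

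Added later, the difference in similarity by age was 0.0225 among pairs within library sets, the trend in peak number had r = 0.599 on chromosomes 1 to 19 and X and 0.573 as residuals from the implied background, and without the first 35 Mb of chromosome 1, 54 regions were called more and 148 less often. Peak ranks rose for 16 and fell for 18 regions by limma; library set as a term gave 21 and 4, set and sex 16 and 4, ranking again among shared regions 18 and 28, with set 2 and 2, with set and sex 2 and 1.

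Leaving out each library in turn gave these ranges: 28 to 105 regions called more often with age, 136 to 327 less often, 185 to 376 separating 18 from 2 months, 195 to 332 for 12 from 2 months, 52 to 120 for 6 from 2 months, 186 to 377 for set 2, 126 to 298 for set 3 and 394 to 594 for the sets within 18 months. The counts of separated regions rise by construction when fewer libraries must share a call. Gene ends ranged from 0 to 1, lists by neighbouring peaks from 0 to 1, r of the gene-end share from -0.0711 to 0.203, peaks at 12 minus 2 months from -760.4 to 3598, ranks that rise from 8 to 58 and that fall from 11 to 54, and r for peaks near Lef1 from -0.149 to 0.144.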

Other observations

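The rank analysis below was chosen after the region trends were seen, as were the genes named in it and the tests on splits for ranks and for gene ends, while the other counts over splits of the samples were set in advance. Regions near H2-Q4 and H2-Q7, class I histocompatibility genes close to H2-Q6 on chromosome 17, moved up the peak lists with age. Peaks were ranked by strength within each equal-length list (rank 1 the strongest), and the ranks of the 11230 regions called in all 20 libraries were fitted on age with limma. A region 8863 bp from H2-Q4 (chromosome 17, 35393537 to 35394549) had a mean rank of 10268 ± 5878 at 2 months (SD, n = 4), 7542 ± 3518 at 6 months (n = 5), 4218 ± 1982 at 12 months (n = 5) and 1357 ± 754 at 18 months (n = 6; limma adjusted p = 0.000901, with set as a term 0.0116). At an end of H2-Q7 (chromosome 17, 35438745 to 35439715) the mean rank went from 17181 ± 2394 at 2 months to 6052 ± 2912 at 18 months (limma adjusted p = 0.00176, with set 0.0222). Ranked again among the shared regions with set as a term, neither passed (limma adjusted p = 0.0557 and 0.129). These genes are near-identical copies, so reads could move between them.

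The calls on ranks depended on the settings. limma called 16 regions stronger and 18 weaker with age, and 1501 had an unadjusted p under 0.05; 1 of 100 assignments of the ages gave the 34, the highest other 1, so chance can be excluded for that fit. With library set as a term it called 21 stronger and 4 weaker, and 4 regions were called by both fits. Over 6 settings, 1 region was called in all, on chromosome 13 (107607211 to 107608057), with no end of a protein-coding gene within 50 kb; its mean rank went from 15204 ± 2667 at 2 months (n = 4) to 4618 ± 1868 at 18 months (n = 6; limma adjusted p = 0.000317, with set 0.0058). Without 2 months replicate 4 it called 58 stronger and 54 weaker, without 2 months replicate 1 it called 8 stronger, and without 18 months replicate 2 it called 8 stronger and 11 weaker. Within set 2, limma called 65 regions stronger and 70 weaker at 18 than at 12 months. Every library of 18 months there also had a lower implied background, a higher median fold and an earlier library number. Age cannot be told apart from these for the 65 and 70 regions. Between 6 and 2 months in set 3 limma called 0 and 0, with 743 at an unadjusted p under 0.05, and between the sets within 18 months 1 and 0.

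Other splits of the same libraries were counted for each comparison of regions. Splits between ages mix the library sets, so they test chance and do not exclude set. Chance can be excluded for 18 against 2 months, where 1 of 100 splits, the real one, separated 167 regions and the highest other 31, and for 12 against 2 months, where 1 of 100 separated 164 and the highest other 51. It can be excluded too for the sexes, where 1 of 100 splits gave the 9 regions and the highest other 0. For gene ends, counted at an unadjusted p under 0.05 because 0 had passed adjustment, 1 of 100 free assignments of the ages gave 181 genes. The highest other gave 170, close to it, so chance is unlikely for this count but not excluded. When ages were reassigned only within library sets, 5 of 100 draws, the real one included, gave as many, the highest 197, so library set may account for that count. For 12 against 18 months in set 2, 1 of 56 splits, the real one, gave 139 and the highest other 73. That share is the smallest that 56 splits allow, so chance is unlikely there but not excluded. The real split also parts these libraries by implied background and by library number. For 6 against 2 months chance cannot be excluded, where 10 of 100 splits gave at least 41 and the highest other 76. Nor can it for set 3, where 7 of 56 gave at least 105 and the highest other 170. The sets within 18 months make 10 splits, too few for a share under 0.05: the real split separated 225 regions and the highest other 176.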
